A study of Mus musculus with 2 samples.

How the data were processed

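The study measured RNA of single cells by 10x Chromium 3' v3 droplet sequencing, in 2 libraries of mouse cells taken from femoral marrow and from the surface of the implant, 1 library from the Mg nail group and 1 from the Mg-TAGelMA nail group. The deposited matrices hold raw UMI counts per gene and barcode, without normalization. The deposited gene tables pair each gene identifier with its symbol, and the deposited barcode lists name the matrix columns; these other files carry no measured unit. Per the file headers, the counts were made with Cell Ranger 5.0.0 for the Mg library and Cell Ranger 7.0.1 for the Mg-TAGelMA library. The authors' notes name STAR and the mm10 genome. Whether intronic reads were counted, the annotation release and any pooling of mice are not stated. Both matrices list 32285 genes, and no barcode had fewer than 500 UMIs.

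Barcodes were kept when they had at least 200 detected genes and at most 15% mitochondrial counts. Doublets called by scrublet in each library were removed, 212 in the Mg library (2.55%) and 259 in the Mg-TAGelMA library (3.44%). Over 15% mitochondrial counts were found in 1091 barcodes of the Mg library and 62 of the Mg-TAGelMA library, and fewer than 200 genes in 189 and 22. Kept cells had a median of 3805 UMIs in the Mg library and 6765.5 in the Mg-TAGelMA library. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together on 2000 variable genes, 30 principal components and 15 nearest neighbours at a Leiden resolution of 1 (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with no integration. The 37 clusters were named from 26 marker lists. A cluster took the name of the list with the highest mean log2 level relative to the mean of the clusters, when at least 3 of its markers were raised over 2-fold with at least 5 UMIs. It stayed unnamed otherwise, or when its 10 leading genes held more markers of another lineage, or when its depth was low and its leading genes held 0 of its own markers. Stages of the neutrophil lineage counted as 1 lineage in this step, as did those of the B lineage and the dendritic types. Names are written "-like" because no protein or sort supports them.

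Shares of kept cells per class were given with exact Clopper-Pearson 95% intervals, and the ratio of 2 shares with its exact conditional interval. For gene ratios, raw counts were summed per library and class and scaled to the class total (CPM), for classes with at least 100 cells in each library and for all cells together. Ratios are Mg-TAGelMA over Mg with exact conditional binomial 95% intervals. A count of 0 was set to 3 counts, which gives a lower bound of the fold. A gene was past the size rule when its interval lay wholly beyond 2-fold up or down and it reached at least 50 CPM in the higher library. This describes 2 libraries and is not a test of the nails, because cells are not replicates. TMM scaling (edgeR 4.0.16) and median-ratio size factors (DESeq2 1.42.0, R 4.3.3) were applied to the same sums.

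For each of 27 gene lists fixed beforehand, the median log2 ratio of members with at least 10 CPM in either library was compared with 10000 random lists of the same size and mean expression. A list with at least 5 measured members was called when its median lay at or below the 2.5th or at or above the 97.5th percentile. Lists with fewer measured members gave no value, as osteoblast and bone matrix genes did in every class. Genes named by rank were the 10 highest and 10 lowest log2 ratios past the size rule in all cells, and the 5 highest and 5 lowest in each class with at least 300 cells in each library, there only when the CPM reached 25% of the all-cell CPM in the library where the gene was higher. Immunoglobulin, T cell receptor, haemoglobin, mitochondrial, ribosomal protein, Xist, Tsix and Y-linked genes and models without a symbol of their own were not named by rank. List members were named by the largest log2 ratio among those past the size rule. Bach2, Osm, S100a8, Gm42418, C1qa, C1qb, Fth1, Ftl1 and the first genes with at most 8 kb of intron were named outside these rules, after their values were seen.

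Intron lengths and positions came from GENCODE vM21 (GRCm38, the assembly of mm10), matched by gene identifier for 32235 of 32285 genes (99.8%). Calls were tested on simulated data with 200 changed genes. At a log2 fold of 2 the recovery was 99% or 100% in each class, at 1.5 it was 79% in mature neutrophil-like cells, 92% in T-like cells and 98% to 100% in the others, and 0 unchanged genes were called. The rule asks for an interval wholly beyond 2-fold, so few calls among unchanged genes were built in and specificity was not measured. Alternatives fixed before the data were examined covered the cell filters, doublets, clustering resolution, separate clustering, erythroid cells in the denominator, scaling, CPM minimum, fold bound, thinning to 1000 UMIs per cell and the expression minimum of list members. Added after the data were seen were limits on intron length (on the total of the genes kept and, for 8 kb, on that of all genes), removal of the intron-length trend with 20 bins, random lists matched for intron length, a total without Gm42418 and AY036118, minimums of 1000 and 2000 UMIs, alternatives for 2 monocyte-like clusters, and erythroid-like cells without the cluster that the Mg library lacked. Immature neutrophil-like cells were left out of the gene ratios, since their clusters in the 2 libraries differed in stage. No paired analysis was possible because each group has 1 library. Figures were drawn with matplotlib 3.10.9.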

Results

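Single-cell RNA counts were collected from mice with osteoporotic fractures that carried an intramedullary nail, a rod placed in the marrow cavity of the femur. The cells were femoral marrow cells and cells that adhered to the implant. There were 2 droplet libraries, 1 from the Mg nail group and 1 from the Mg-TAGelMA nail group. GelMA is gelatin methacryloyl, a gelatin hydrogel, and the labels do not spell out TA. The number of mice behind each library, and how marrow and adherent cells were combined, are not stated. The Mg library held 9466 barcodes with 58261391 unique molecular identifiers (UMIs), and the Mg-TAGelMA library held 7591 barcodes with 79890998 UMIs. The median depth was 3499 UMIs per barcode in the Mg library and 6902 in the Mg-TAGelMA library. After filtering, 8107 cells remained in the Mg library and 7264 in the Mg-TAGelMA library. With 1 library per group, no test across the nails was possible, and each interval below is an exact 95% interval of counting error only. Fold differences describe these 2 libraries.

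The comparison asked how the composition and expression of marrow cells differed between the 2 nails. Neutrophil lineage-like cells made up 48.3% of the Mg-TAGelMA library (3512 cells, Clopper-Pearson interval 47.2 to 49.5) and 20.2% of the Mg library (1634 cells, 19.3 to 21.05), a 2.40-fold higher share (2.26 to 2.55). B lineage-like cells made up 24.0% of the Mg-TAGelMA library (1743 cells, 23.02 to 24.99) and 45.9% of the Mg library (3723 cells, 44.8 to 47.0), a 1.91-fold lower share (1.81 to 2.03). Erythroid-like cells were 4.24% of the Mg-TAGelMA library (3.79 to 4.73) and 16.7% of the Mg library (15.9 to 17.5), a 3.94-fold lower share (3.48 to 4.48). The direction held under every setting but the size did not, with folds from 4.69 with no cell filter to 15.7 at a Leiden resolution of 2 and 19.4 with at least 500 detected genes. T-like cells were 4.13% (300 cells, 3.68 to 4.61) against 6.33% (513 cells, 5.81 to 6.88), a 1.53-fold lower share (1.33 to 1.77). Monocyte-like cells were 6.42% against 5.66%, and the interval of their ratio, from 0.994 to 1.29, included no difference. Their ratio was 1.21 (1.07 to 1.38) with no cell filter, 1.19 (1.05 to 1.35) with doublets kept, 1.51 (1.36 to 1.68) at a resolution of 0.5 and 0.795 (0.706 to 0.895) with at least 500 detected genes, so its direction depended on the processing. With an unnamed Mg-TAGelMA cluster led by Pparg and Adgre4 counted as monocyte-like, the shares were 7.31% and 5.66%.

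**Figure D1:**
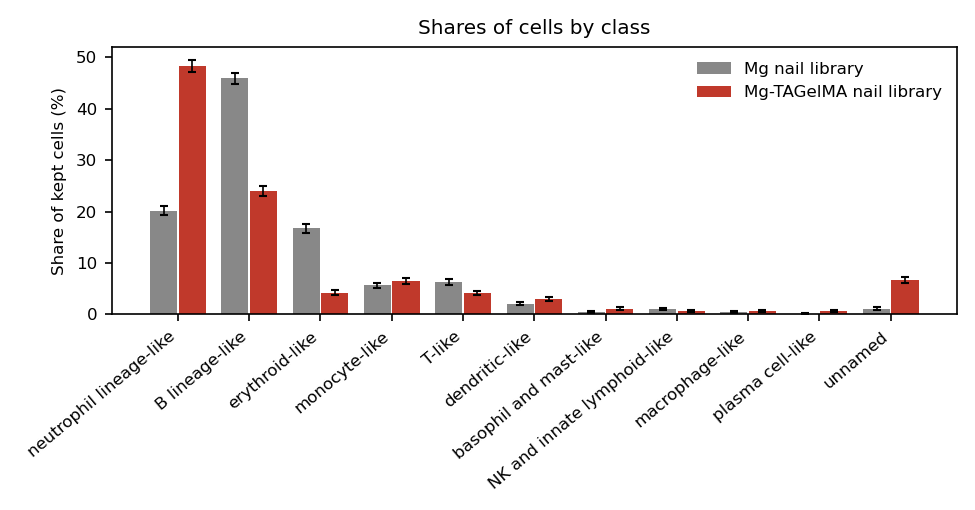
Share of kept cells (%) by class in the Mg nail library (grey) and the Mg-TAGelMA nail library (red), with exact Clopper-Pearson 95% intervals as error bars. Neutrophil lineage-like cells stand at 20.2% and 48.3%, B lineage-like cells at 45.9% and 24.0%.

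Within the neutrophil lineage, cells with mature neutrophil markers were 21.8% of the Mg-TAGelMA library (1587 cells, 20.9 to 22.8) and 4.59% of the Mg library (372 cells, 4.14 to 5.07), a 4.76-fold higher share (4.25 to 5.34). Early granulocyte-like cells, marked by Elane, Prtn3, Ctsg and Mpo, numbered 474 in the Mg-TAGelMA library and 1 in the Mg library. This contrast depended on how 1 Mg cluster was named. Cluster 16 had 3 early granulocyte and 3 immature neutrophil markers among its 10 leading genes, and with doublets kept the counts were 485 and 459, at a Leiden resolution of 2 they were 829 and 421. Cells with immature neutrophil markers such as Ltf, Camp and Ngp formed clusters 4 (823 cells) and 16 (438 cells) in the Mg library and clusters 2 (911 cells) and 12 (540 cells) in the Mg-TAGelMA library. Cluster 2 had 3 mature markers, Mmp8, Mmp9 and Retnlg, among its 10 leading genes, so the immature cells were not compared gene by gene. The mature share depended on the clustering too. It was 0% and 28.8% (Mg and Mg-TAGelMA) at a Leiden resolution of 0.5, and 0.0136% and 35.2% when at least 500 detected genes were required.

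Among B lineage-like cells, the B-like share was 11.9% in the Mg-TAGelMA library and 22.9% in the Mg library, 1.93-fold lower (1.78 to 2.10). B progenitor-like cells, which carried Vpreb1, Igll1 and Rag1, were 12.1% and 23.0%, 1.90-fold lower (1.75 to 2.06). The split within the B lineage depended on the naming of a Mg-TAGelMA cluster led by Agbl1 and Klhl14. With at least 500 detected genes it was named B, and the B progenitor-like shares were 2.84% and 24.2%, the B-like shares 21.6% and 25.4%. Dendritic-like cells were 2.99% in the Mg-TAGelMA library and 2.07% in the Mg library. The Mg dendritic-like cells formed a single cluster that carried both conventional and plasmacytoid markers, so these types were not compared apart. Under other settings these cells fell in clusters with another name or none. The Mg library had 0 dendritic-like cells with at least 500 detected genes, with no cell filter, with doublets kept and at a resolution of 0.5, so the size of this difference depended on the naming. Basophil and mast-like cells numbered 82 against 33, plasma cell-like cells 47 against 12, macrophage-like cells 51 against 36, and NK and innate lymphoid-like cells 48 against 81 (Mg-TAGelMA and Mg). Cells of unnamed clusters numbered 490 against 93. Some of these small counts turned direction. Plasma cell-like cells numbered 51 against 98 at a resolution of 2 and 39 against 109 when each library was clustered on its own, macrophage-like cells 7 against 10 with at least 2000 UMIs, and unnamed cells 99 against 265 with at least 500 detected genes. Most of the 37 clusters held cells of nearly 1 library alone, so classes and not clusters were compared.

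In the sum of all cells, 749 genes were higher in the Mg-TAGelMA library and 303 lower past the size rule (a ratio interval wholly beyond 2-fold and at least 50 CPM, counts scaled to the total of the sum, in the higher library). Inflammatory cytokine and chemokine genes were higher, with 6 of 14 measured members higher past the size rule, 0 lower and a median log2 ratio of 2.79. Il1b (ENSMUSG00000027398, mm10 chromosome 2, 129364570 to 129371139), which encodes interleukin-1 beta, was 25.4-fold higher (23.7 to 27.2), at 392.2 CPM against 15.5. The chemokine genes Ccl3 and Ccl4 were 9.87-fold (9.33 to 10.4) and 8.55-fold (8.19 to 8.93) higher, and the inflammasome gene Nlrp3 was 9.44-fold higher (8.69 to 10.3). Azurophil granule genes had 6 of 10 members higher past the size rule and a median of 1.11, with the proteases Ctsg 4.50-fold (4.37 to 4.64) and Prtn3 3.01-fold higher (2.97 to 3.06).

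B lymphopoiesis genes were lower in the sum of all cells, with 8 of 18 members lower and 2 higher past the size rule and a median log2 ratio of -1.26. Rag1, which encodes the V(D)J recombinase subunit, was 4.55-fold lower, and the pre-B cell receptor gene Vpreb3 was 4.35-fold lower. The members that were higher included Bach2, whose introns span 337 kb, by 3.31-fold. Proliferation genes were lower too, with 13 of 25 members lower past the size rule, 0 higher and a median of -1.06. Mki67 was 4.47-fold, Cenpf 3.76-fold and Mcm2 3.30-fold lower. Osteoclast genes had 2 of 13 members higher and 2 lower past the size rule and a median of 0.71, which was -0.048 over the 3 members with at most 8 kb of intron. Jdp2 was 4.90-fold higher and Car2, a carbonic anhydrase gene also abundant in erythroid cells, 4.25-fold lower. The sums of all cells carry the shares of the classes as well as expression within them.

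By rank, the 10 genes that were furthest higher in all cells were Fgfr2, Lrmda, Nrg1, Pde7b, Antxr2, Kcnq5, Abtb2, Gab2, Plcb1 and Agbl1. Fgfr2 (ENSMUSG00000030849, chromosome 7, 130162451 to 133123350), a fibroblast growth factor receptor gene, was 397-fold higher (201 to 920), with 4364 UMIs against 8. The annotated introns of these genes spanned from 142 kb in Antxr2 to 2951 kb in Fgfr2. Whether all counts within such long spans, that of Fgfr2 above all, come from transcripts of the named gene was not tested. The 10 genes furthest lower were Lars2, Hist1h3c, Hist1h3f, Slc4a1, Hist2h2bb, Hist1h4h, Alas2, Hist1h1a, Hist1h2ab and Hist1h4d, of which 7 encode histones. Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), the mitochondrial leucyl-tRNA synthetase gene, was 23.8-fold lower (23.1 to 24.4). Slc4a1 and Alas2, genes of red cell anion exchange and haem synthesis, were 10.1-fold (9.62 to 10.6) and 9.54-fold lower (8.87 to 10.3). Gm42418, a gene model that overlaps ribosomal RNA sequence, took 6.90% of the UMIs of the Mg library and 0.110% of the Mg-TAGelMA library. Lars2, like Gm42418, was higher in the Mg library in each class ranked below. Whether the Lars2 counts come from the synthetase transcript was not tested.

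The ratio between the libraries followed intron length in each class. Genes with over 64 kb of annotated intron had a median log2 ratio from 0.67 in mature neutrophil-like cells to 1.30 in B-like cells, and genes with 2 to 8 kb had medians from -0.53 in B-like cells to 0.10 in erythroid-like cells. Spearman's rho between the log2 ratio and intron length, across genes, which are not independent replicates, ranged from 0.27 in mature neutrophil-like cells to 0.61 in B-like cells. The file headers name Cell Ranger 5.0.0 for the Mg library and 7.0.1 for the Mg-TAGelMA library, so the counting software differed between the nails. The fold of a gene with long introns can reflect the counting as well and is not read as expression alone. Among genes with at most 8 kb of intron, a choice made after the data were seen, 87 of the 749 higher and 130 of the 303 lower genes in all cells remained, and 111 and 187 passed when these genes were scaled to their own total. By the same rank rule and their own total, the first 6 of these on the higher side were Asprv1, Prg2, Mir142hg, Il1b, Cstdc4 and Acod1. Prg2, an eosinophil granule gene, was 29.8-fold higher (25.1 to 35.7), and Acod1, the itaconate-producing enzyme gene, 17.3-fold higher (15.4 to 19.5). Prg2, Ccl3 and Ccl4 were also among the 10 leading genes of the basophil and mast-like cluster, which held 82 Mg-TAGelMA and 33 Mg cells.

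**Figure D2:**
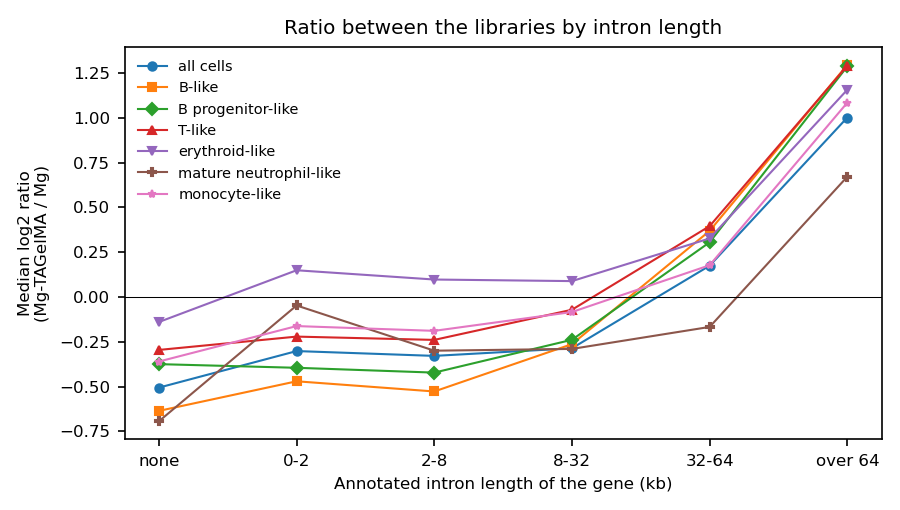
Median log2 ratio (Mg-TAGelMA over Mg) of genes grouped by annotated intron length (kb), 1 line per cell class. Every line is highest for genes with over 64 kb of intron, where the medians run from 0.67 in mature neutrophil-like to 1.30 in B-like cells.

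Mature neutrophil-like cells had higher inflammatory and interferon genes in the Mg-TAGelMA library. In this class TMM scaling moved all log2 ratios by 0.35 against CPM, and list medians are given on the TMM scale, gene ratios on the CPM scale. Inflammatory genes had 5 of 15 measured members higher and 1 lower past the size rule and a median of 1.999. Il1b was 5.95-fold higher (5.35 to 6.64), Ccl4 13.01-fold (9.43 to 18.5) and Ccl3 9.03-fold (5.70 to 15.3). Csf1, the macrophage colony-stimulating factor gene, was 20.5-fold higher (5.65 to 170) on 2 UMIs in the Mg library. The member that was lower was the cytokine gene Osm, with a log2 ratio of -1.46. Interferon response genes had 4 of 25 members higher and 1 lower and a median of 1.13, with Ifitm3 4.64-fold (4.04 to 5.36), Rtp4 4.21-fold (2.65 to 7.13) and Isg15 3.70-fold higher (2.36 to 6.18) and Slfn4 3.45-fold lower.

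Specific and gelatinase granule genes had 6 of 17 members lower and 0 higher past the size rule in mature neutrophil-like cells, with a median of -0.39. Olfm4 was 4.70-fold lower, the lactoferrin gene Ltf 4.48-fold, the NADPH oxidase gene Cybb 3.19-fold and Cd177 2.53-fold. Over the 8 members with at most 8 kb of intron, however, the median was 0.45 on the CPM scale against -0.74 over all members, so the sign depended on the members with longer introns. Phagocytosis genes had 4 of 10 members higher, 0 lower and a median of 1.57, led by Tyrobp at 5.53-fold (5.05 to 6.08) and Dock2 at 4.69-fold (4.09 to 5.41), whose introns span 546 kb. Magnesium transport genes had a median of -0.997 over 11 members. The 1 member past the size rule, Cnnm2, went the other way, at 103-fold higher (28.4 to 849) on 2 UMIs in the Mg library, with 113 kb of intron. Proliferation genes had 2 of 24 members lower and a median of -0.75, and both members stood below 25% of their all-cell level. By rank, Cnnm2, Lrmda, Arl15, Dusp16 and Cables1 were furthest higher and Lars2, Hist1h1e, Trim56, Klhl9 and Dmwd furthest lower. In all, 380 genes were higher and 284 lower past the size rule. The balance depended on the processing, at 544 and 133 with TMM scaling, 287 and 533 with a total without Gm42418 and AY036118, and 45 and 94 among the genes with at most 8 kb of intron (37 and 235 when scaled to their own total). All but 1 of the cells compared sat in different clusters by library. The Mg cells were in cluster 19, led by G0s2 and Adam8, and the Mg-TAGelMA cells in cluster 5 (808 cells), led by Il1b and Acod1, and cluster 6 (778 cells), led by Retnlg, so their stage or state may differ too. The Mg cells of this class had a median of 1426.5 UMIs and the Mg-TAGelMA cells 4816.

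Monocyte-like cells of the Mg-TAGelMA library had higher chemokine, metallothionein and matrix remodelling genes and lower proliferation and immediate early and dissociation stress genes. The latter list, called immediate early genes below, holds genes that cell handling raises as well, and the libraries were prepared apart, so its values are not read as activation in tissue. Of the 466 Mg-TAGelMA monocyte-like cells, 459 formed cluster 15, which held 0 Mg cells, so the cells compared may differ in stage or state. Inflammatory genes had 5 of 18 members higher, 0 lower and a median log2 ratio of 1.49. Ccl7 was 26.4-fold (13.3 to 61.7), Ccl2 4.47-fold (3.92 to 5.12), Il1b 3.48-fold (2.98 to 4.08) and Ccl4 3.11-fold higher (2.79 to 3.48). The metallothionein list, genes that bind or carry zinc, had 2 of 10 members higher, 0 lower and a median of 0.62, with Mt2 15.3-fold (9.91 to 24.95) and Mt1 4.59-fold higher (4.20 to 5.03). Extracellular matrix remodelling genes had 4 of 12 members higher, 0 lower and a median of 2.14, led by thrombospondin 1 (Thbs1, 8.86-fold, 7.95 to 9.90), the gelatinase gene Mmp9 (7.98-fold, 5.83 to 11.2) and the urokinase receptor gene Plaur (5.46-fold, 4.82 to 6.21). Mmp9 stood at 94.8 CPM in these cells beside 469.8 CPM in all cells, a level that free RNA from neutrophils also reaches. Angiogenesis genes had 4 of 8 members higher, 0 lower and a median of 1.06, with Vegfa 3.92-fold higher (2.88 to 5.46). NF-kB target genes had 5 of 16 members higher and 1 lower and a median of 0.58, with Bcl3 6.65-fold (4.87 to 9.28) and Cd83 4.31-fold higher (3.28 to 5.75).

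Proliferation genes in monocyte-like cells had 16 of 25 members lower, 0 higher and a median of -1.63. Top2a was 13.3-fold, Cdk1 8.23-fold, Cenpf 7.66-fold and Ccna2 6.73-fold lower. Immediate early genes had 7 of 24 members lower and 1 higher and a median of -0.54. The transcription factor gene Egr1 was 3.25-fold lower, Btg2 3.09-fold and Jun 2.89-fold, whereas Ier3 was 3.23-fold higher (2.77 to 3.79). Interferon response genes had a median of 0.77 over 28 members, with 0 past the size rule on either side. By rank, Snx24, March3, Lrmda, Fmnl2 and Chst11 were furthest higher, and Hist1h3c, Hist1h2ab, Fabp4, Anln and Lars2 furthest lower. The place of Fabp4 depended on the naming. It marked a cluster of 93 Mg cells with Ace and Ear2, whose Mg-TAGelMA counterpart, 65 cells led by Pparg and Adgre4, stayed unnamed and was not counted; at a resolution of 0.5 both formed 1 monocyte-like cluster. The log2 ratio of Fabp4 was -2.76 with the counterpart counted and -0.36 without the Mg cluster. Without that cluster the inflammatory median was 1.36 and the proliferation median -1.77. Among genes with little intron, chosen after their values were seen, the complement genes C1qb and C1qa were 48.6-fold (18.8 to 180) and 38.4-fold higher (16.3 to 119), on 4 and 5 UMIs in the Mg library. In all, 625 genes were higher and 127 lower past the size rule, of which 38 and 63 had at most 8 kb of intron (57 and 93 when these genes were scaled to their own total). The balance thus turned among genes with little intron.

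**Figure D3:**
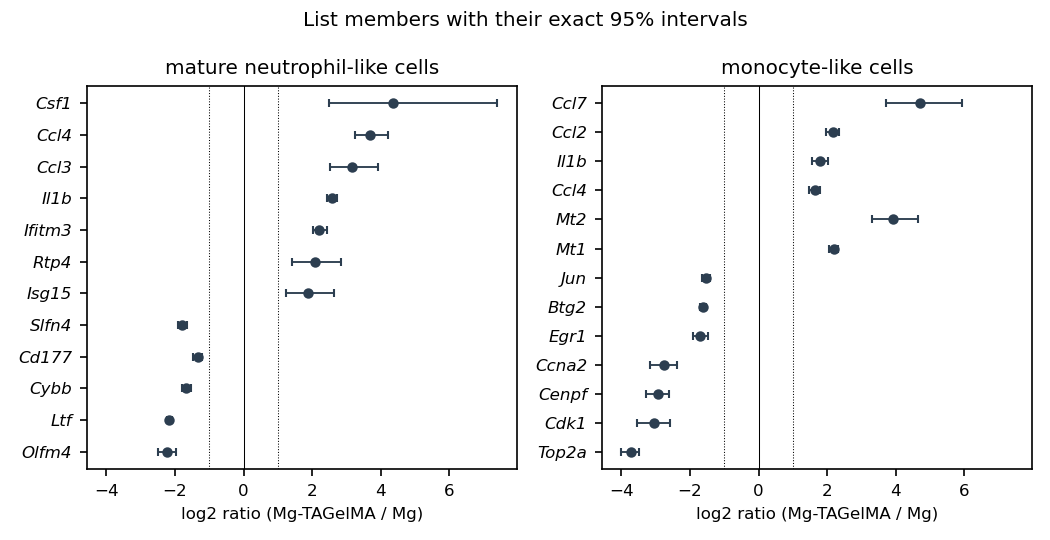
Log2 ratio (Mg-TAGelMA over Mg) of chosen list members past the size rule in mature neutrophil-like cells (left) and monocyte-like cells (right), with exact conditional binomial 95% intervals as bars and dotted lines at 2-fold. Of the members drawn, Csf1 at 4.36 and Ccl7 at 4.72 are furthest to the right, Olfm4 at -2.23 and Top2a at -3.73 furthest to the left. Osm, Ier3 and Cnnm2, which went against their lists, are not drawn, and the fold of Cnnm2 was larger than that of Csf1. Other members past the size rule, such as Tyrobp and Dock2, are not drawn either.

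B-like cells had higher immediate early and dissociation stress genes in the Mg-TAGelMA library, with 8 of 22 members higher, 0 lower and a median log2 ratio of 1.12. Socs3, a feedback inhibitor of cytokine signalling, was 15.8-fold higher (10.2 to 25.8), Atf3 14.2-fold (9.47 to 22.3), Nr4a1 11.6-fold (9.75 to 13.9) and Fos 3.98-fold (3.50 to 4.54). Proliferation genes had a median of -0.98 over 24 members, with 3 lower past the size rule, among them Mki67 by 4.88-fold and Top2a by 3.91-fold; all 3 stood below 25% of their all-cell level. By rank, Slc15a2, Raet1e, Cfap43, Fgfr2 and Slc2a13 were furthest higher. Raet1e, Fgfr2 and Slc2a13 had 0 UMIs in the Mg B-like cells, so they were at least 351-fold, 190-fold and 131-fold higher against 3 counts. Lars2, Fam129c, Arid3a, Spib and Psme2b were furthest lower, and Spib, a B cell transcription factor gene, was 7.94-fold lower (6.94 to 9.12). In all, 883 genes were higher and 232 lower past the size rule, of which 51 and 122 had at most 8 kb of intron. Of the 861 Mg-TAGelMA B-like cells, 856 formed cluster 3, which held 0 Mg cells, so stage or state may differ here too.

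B progenitor-like cells had higher immediate early, NF-kB and MHC class II genes and lower proliferation genes in the Mg-TAGelMA library. The cells compared may differ in stage, since 675 of the 882 Mg-TAGelMA cells formed cluster 7, which held 0 Mg cells and was named B with at least 500 detected genes. TMM scaling moved log2 ratios in this class by -0.24, and list medians are on the TMM scale. Immediate early genes had 8 of 23 members higher and 1 lower and a median of 1.19, with Fosb 5.86-fold (4.95 to 6.97), Klf4 4.12-fold (3.602 to 4.71) and Klf2 3.28-fold higher (3.13 to 3.43). NF-kB targets had 5 of 14 members higher, 0 lower and a median of 1.38, with Relb 8.25-fold (7.28 to 9.37) and the apoptosis inhibitor gene Birc3 4.15-fold higher (3.83 to 4.50). MHC class II presentation genes had 3 of 13 members higher, 0 lower and a median of 0.88. The invariant chain gene Cd74 was 4.45-fold (4.26 to 4.65), Cd86 27.1-fold (18.6 to 41.1) and Ctss 2.64-fold higher (2.35 to 2.97). Proliferation genes had 5 of 25 members lower, 0 higher and a median of -1.18, with Mki67 3.36-fold, Mcm2 2.90-fold and Cenpf 2.66-fold lower. Oxidative phosphorylation genes had a median of -0.72 with 0 of 27 members past the size rule, and this median fell within the range of random lists matched for intron length. By rank, Fgfr2, Trim17, Slc25a18, Sidt1 and Agbl1 were furthest higher, and Lars2, Hist1h3c, Hist1h4h, Hist1h3f and Hist1h2ab furthest lower. In all, 841 genes were higher and 87 lower, against 698 and 266 with TMM scaling, and 68 and 56 of them had at most 8 kb of intron.

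T-like cells had higher NF-kB target genes in the Mg-TAGelMA library, with 5 of 16 members higher, 0 lower and a median of 1.19 on the TMM scale, which moved log2 ratios by -0.10. Relb was 6.92-fold (5.40 to 8.98), Birc3 5.35-fold (4.40 to 6.55) and Tnfaip3, a feedback inhibitor of NF-kB, 4.97-fold higher (4.41 to 5.60). Hypoxia response genes had 2 of 12 members higher and 1 lower and a median of 0.87, with Mxi1 7.91-fold higher (5.84 to 10.9) and Pdk1 2.76-fold lower. The 2 members with at most 8 kb of intron had a median of -1.03 on the CPM scale, the other sign. The median of cytotoxic genes, 0.41 over 14 members, lay within the range of random lists matched for expression and above those matched for intron length too, and with doublets kept it was 2.06 on the CPM scale against 0.51, so this list was left open. The granzyme gene Gzmb was 15.9-fold (9.03 to 30.4) and Fasl 3.08-fold higher (2.23 to 4.29). By rank, Oprm1, Lrmda, Fhit, Kcnq5 and Raet1e were furthest higher and Lars2, Trim56, Ccr9, Ttf1 and Fam78a furthest lower, the chemokine receptor gene Ccr9 by 4.25-fold (2.94 to 6.29). In all, 790 genes were higher and 62 lower past the size rule, of which 48 and 27 had at most 8 kb of intron. Of the 300 Mg-TAGelMA T-like cells, 294 formed cluster 21, which held 0 Mg cells, so stage or state may differ here too.

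Erythroid-like cells had lower proliferation genes and higher immediate early and NF-kB genes in the Mg-TAGelMA library. TMM scaling moved log2 ratios by -0.48 here, and list medians are on the TMM scale. Iron handling genes had 2 of 12 members lower and 1 higher (Lcn2, below 25% of its all-cell CPM) and a median of -0.99, with the mitochondrial iron importer gene Slc25a37 4.10-fold and the transferrin receptor gene Tfrc 2.46-fold lower. The 3 members with at most 8 kb of intron had a median of 0.27 on the CPM scale, the other sign. Proliferation genes had 3 of 25 members lower, 0 higher and a median of -1.16. Immediate early genes had 13 of 22 members higher, 0 lower and a median of 1.40, with Atf3 13.01-fold (9.53 to 18.1) and Junb 7.31-fold higher (6.73 to 7.94). NF-kB targets had 7 of 14 members higher, 0 lower and a median of 2.58, with Relb 22.2-fold higher (17.4 to 28.9). Of these, 11 and 6 reached 25% of their all-cell CPM. By rank, Tex14, Prg2, Lrmda, Cxcl10 and Zswim6 were furthest higher and Lars2, Hist1h3c, Hist1h4h, Hist1h3b and Hist2h2bb furthest lower. In all, 571 genes were higher and 71 lower, against 359 and 225 with TMM scaling, and 73 and 40 of them had at most 8 kb of intron. Without cluster 28 below, 457 were higher and 186 lower, and only 258 and 36 of these had passed with it. The cells compared may differ in stage, since 96 of the 308 Mg-TAGelMA cells formed cluster 28, which held 0 Mg cells and had a median of 40806 UMIs. This cluster held 89.4% of the Mg-TAGelMA UMIs of the class, so the ratios above describe it more than the other cells. Without it, a choice made after the data were seen, the medians on the CPM scale were -1.13 for proliferation, 2.30 for immediate early and 2.74 for NF-kB genes, against -0.67, 1.89 and 3.06 with it. The remaining Mg-TAGelMA cells were few and shallow. A further 156 of the 308 and 421 of the 1355 Mg cells formed cluster 10, which barely carried the name, with an erythroid score of 0.094, a median of 857 UMIs and Ighg1 as its first gene. Cluster 10 held 35.8% of the Mg and 5.64% of the Mg-TAGelMA UMIs of the class, and no ratios were made without it. The matching cluster was unnamed with doublets kept and with at most 10% mitochondrial counts. With each library clustered on its own, 195 Mg-TAGelMA cells, with a median of 842 UMIs, were named eosinophil and only 50 erythroid. Whether these 195 are the cells of cluster 10 was not tested. The rank of Prg2, an eosinophil granule gene, is therefore not read as erythroid expression.

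Neutrophil transcripts were also counted in cells that should lack them. Specific granule genes had medians of 1.39 in B-like, 1.75 in B progenitor-like (TMM scale) and 0.86 in T-like cells (TMM scale). In each of these classes, 0 of the members past the size rule reached 25% of their all-cell CPM, and the same held for the inflammatory genes. Of the specific granule members past the size rule, 0 of 11 reached this level in erythroid-like cells and 2 of 7 in monocyte-like cells. S100a8, a neutrophil gene, stood at 4252 CPM in Mg-TAGelMA B-like cells and 950 in Mg B-like cells, beside 51990 and 14680 in all cells. These values were read as background from free RNA and not as expression by lymphocytes or erythroid cells, and in monocyte-like cells the sources were not told apart.

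Across the 27 gene lists and 7 classes, 170 combinations had at least 5 measured members. Of these, 58 medians lay above and 12 below the range of matched random lists, where 8.5 would by chance if combinations were independent. With random lists matched for intron length as well, 69 of these 70 stayed outside on the same side and 18 further ones fell outside, 87 in all. The combinations are not independent, since all cells hold the other classes and lists share genes. Genes of the random lists were drawn independently, whereas members of a gene list can vary together. Their range may therefore be too narrow in each combination, and it holds no variation between libraries. Some calls were also read as background above, so 8.5 is only a guide.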

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

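The tests of intronic reads, nuclear RNA, damaged cells and transcripts without a poly(A) tail below were chosen only after the results they measure had been seen; the others were set before.

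The specific and gelatinase granule genes differed in direction between classes, with median log2 ratios (CPM scale) of 1.39 in B-like, 1.99 in B progenitor-like, 0.97 in T-like, 1.72 in erythroid-like and 1.68 in monocyte-like cells and -0.74 in mature neutrophil-like cells, where the 8 members with at most 8 kb of intron had 0.45; the difference was not tested. In the B-like, B progenitor-like, T-like and erythroid-like cells 0 of the members past the size rule reached 25% of their all-cell CPM, and in monocyte-like cells 2 of 7 did. The values of the former classes were read as background from free RNA, so the direction is not read as a difference in expression between classes. Immediate early and dissociation stress genes, which cell handling raises as well, had medians of 1.12 in B-like, 1.43 in B progenitor-like and 1.89 in erythroid-like cells and -0.54 in monocyte-like cells, a difference that was not tested either. Barcodes left out for over 15% mitochondrial counts were 11.5% of the Mg library (10.9 to 12.2) and 0.817% of the Mg-TAGelMA library (0.627 to 1.05), which sets them above the level that a count of 0 allows. When clustered with the rest, 892 of the 1081 such Mg barcodes that were not doublets (82.5%) fell in unnamed clusters, with a median of 875 UMIs.

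Genes with long introns were higher in the Mg-TAGelMA library in each class. The nuclear transcripts Malat1, Neat1, Kcnq1ot1 and Xist lay below the genes with over 64 kb of intron. The median log2 difference was -1.78 (quartiles -2.09 and -1.38), with 22 of 23 values under -0.5. This argues against more nuclear RNA in the Mg-TAGelMA library only as far as these transcripts stand for it. Xist and Y-linked counts differed between the libraries in all kept cells (Xist 1212 CPM in Mg and 588 in Mg-TAGelMA, Y-linked genes 0 and 53 UMIs). A difference in the capture of transcripts without a poly(A) tail, considered below, was not told apart from this either. Intronic reads counted in 1 library and not in the other remain a candidate explanation, since the lowest rho over the classes was 0.27. A change of transcription caused by the nail stays open and untested, as the Cell Ranger version goes with the nail.

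The neutrophil-lineage share was larger and the B-lineage share smaller in the Mg-TAGelMA library. Loss of low-RNA neutrophils below the UMI minimum of the shallower Mg library is argued against. With the minimum raised to 1688 UMIs in the Mg-TAGelMA library alone, its neutrophil-lineage share was 49.9% (48.7 to 51.0), although the depth ratio behind this, 3.38, came from cells above the minimum. Whether the cell filters removed neutrophils cannot be told, since most of the Mg cells brought back fell in unnamed clusters. With no cell filter the log2 ratio of the shares was 1.41, and 47.9% of the Mg-TAGelMA library was neutrophil lineage-like. In the Mg library 18.1% were then neutrophil lineage-like and 16.6% unnamed, which together stay below that share. If the other names hold, the filters thus do not account for the whole difference, even with every unnamed Mg cell taken as a neutrophil. Unnamed cells then numbered 1531 in the Mg library and 655 in the Mg-TAGelMA library, against 93 and 490 with the filters. The lineage of these cells was not tested. A different mix of marrow and implant-adherent cells, and an effect of the nail, stay open and untested.

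Gm42418 and AY036118 were higher in the Mg library in each class, and Gm42418 was found in 8107 of 8107 Mg cells at a median share of 7.88%. Over the kept Mg cells the Gm42418 share did not rise with the mitochondrial share (rho -0.23). Whether damaged cells carry more of it cannot be told from this value. Barcodes above the mitochondrial limit had been left out, and both are shares of the same UMI total, so a rise in either lowers the other. As every kept Mg cell had Gm42418, it was not confined to the barcodes left out. Transcripts without a poly(A) tail may have been captured more in the Mg library, since replication-dependent histone genes lay below the proliferation list by a median difference of -0.96 over the classes. Free RNA cannot be told apart from RNA of the cells, because the log-log slope of Gm42418 on other UMIs, 0.64 (0.62 to 0.65), lay between the bounds set for either. An effect of the nail stays open and untested.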

How the results depend on the processing

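The UMI minimums, intron limits, trend removal, changed monocyte-like and erythroid-like classes and total without Gm42418 and AY036118 below were chosen after the data were seen. Shares were scored for 6 classes (neutrophil lineage, mature neutrophil, B lineage, erythroid, monocyte and T), of which only the monocyte-like share, whose interval included no difference, changed sign. Outside these, the log2 ratio turned for immature neutrophil-like cells from 0.36 to -0.62 (at least 500 detected genes), -0.51 (no cell filter) and -0.63 (resolution 0.5), for plasma cell-like cells to -0.78 (resolution 2) and -1.32 (separate clustering) and for macrophage-like cells to -0.56 (at least 2000 UMIs). Of 60 alternative log2 ratios of shares 24 stayed within the interval of the reported value, and the others follow. For neutrophil lineage-like, mature neutrophil-like, B lineage-like, erythroid-like and monocyte-like cells in turn, at least 500 detected genes gave 1.39, 11.34, -1.03, -4.28 and -0.33. For the first 4 of these classes, no cell filter gave 1.41, 2.04, -0.69 and -2.23, separate clustering 1.40, 1.68, -0.83 and -4.06, and at least 2000 UMIs 1.49, 3.73, -1.05 and -2.54. Without erythroid cells the neutrophil lineage, mature neutrophil, B lineage and monocyte values were 1.06, 2.05, -1.14 and -0.021. A resolution of 2 gave 1.37 (neutrophil lineage), -3.97 (erythroid) and -0.36 (T). For mature neutrophil-like and erythroid-like cells, at most 10% mitochondrial counts gave 1.59 and -2.51 (monocyte -0.14), doublets kept 1.61 and -2.56 (T -0.28), a resolution of 0.5 gave 9.60 and -2.46 (monocyte 0.60, T -0.41) and at least 1000 UMIs 2.65 and -2.33. The mature neutrophil-like name thus depended on the clustering, while the neutrophil lineage stayed between 1.06 and 1.49; the cause was not tested. Counts of genes past the size rule follow for all cells, B-like, B progenitor-like, T-like, erythroid-like, mature neutrophil-like and monocyte-like cells in turn. They were 5030, 2718, 3005, 1745, 2541, 1101 and 1816 with no filter on low values, and 1916, 1864, 1696, 1378, 1072, 1173 and 1257 beyond 1.5-fold, where more genes can pass. They were 298, 199, 177, 110, 160, 272 and 150 with at most 8 kb of intron and 149, 108, 126, 60, 121, 150 and 97 with at most 2 kb, both scaled to the total of the genes kept, so fewer genes were run and the scale changed as well. The 8 kb limit alone, on the total of all genes, gave 217, 173, 124, 75, 113, 139 and 101. At least 100 CPM gave 619, 699, 601, 554, 331 and 476 (all but mature neutrophil), again with fewer genes run. Trend removal gave 698, 596, 505 and 400 (B, B progenitor, T, erythroid), thinning 540 (T) and 448 (monocyte), and doublets kept 996 (erythroid); their cause was not tested. The other 44 counts stayed within 1.5 times the reported ones in total, though without the erythroid-like cluster of 1 library 457 were higher and 186 lower against 571 and 71, and at least 500 detected genes left too few erythroid-like and mature neutrophil-like cells of 1 library for a count. TMM scaling kept the totals and moved the part that was higher from 90.6% to 72.4% in B progenitor-like, from 88.9% to 61.5% in erythroid-like and from 57.2% to 80.4% in mature neutrophil-like cells, where a total without Gm42418 and AY036118 gave 287 higher and 533 lower. Of list medians 778 stayed and 111 moved, and of named gene ratios 362 stayed and 156 moved. The called median of specific granule genes in mature neutrophil-like cells reversed over members with at most 8 kb of intron, to 0.13 on their own total and 0.45 on that of all genes. With fewer than 5 such members, which were not scored, iron handling in erythroid-like cells (0.27), hypoxia in T-like cells (-1.03) and angiogenesis (-0.58) and osteoclast genes (-0.048) in all cells took the other sign too. At this depth a log2 fold of 1.5 was recovered for 79% of simulated genes in mature neutrophil-like cells, so smaller differences there were not detectable in full.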

Other observations

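Every value here was chosen after the data were seen. The few plasma cell-like cells differed in isotype. Igha, the IgA heavy chain gene, led in both libraries, with 52.7% of the heavy-chain constant UMIs in 12 Mg cells and 49.5% in 47 Mg-TAGelMA cells. Ighm was 36.4% in the Mg cells and 3.97% in the Mg-TAGelMA cells. Ighg2c was 0.0824% (20 UMIs, leading in 0 cells) and 24.4% (32136 UMIs, leading in 10 cells), and Ighg2b 10.7% and 18.9%. With so few cells, 1 clone can set such a share.

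Few cells carried several UMIs of the genes of bone and vessel looked at. Cells with at least 5 UMIs numbered 2 in the Mg and 2 in the Mg-TAGelMA library for the bone collagen gene Col1a1, 12 and 1 for the stromal chemokine gene Cxcl12, 2 and 3 for the endothelial gene Cdh5, and 0 and 2 for the osteoclast protease gene Ctsk. Acp5, an osteoclast enzyme gene that other marrow cells express as well, reached 5 UMIs in 147 and 39 cells, and Pecam1, an endothelial gene that leukocytes express too, in 54 and 584. With each library clustered on its own, 193 Mg cells were named osteoblast lineage and 379 stromal, names that no cluster had in the joint clustering. The same setting named 195 Mg-TAGelMA and 0 Mg cells eosinophil, and 164 and 83 stem and progenitor, also names absent from the reported clustering. Osteoblasts, osteoclasts and endothelial cells were not compared.

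In mature neutrophil-like cells the ferritin genes Fth1 and Ftl1 were 4.80-fold (4.56 to 5.06) and 3.599-fold (3.33 to 3.90) higher in the Mg-TAGelMA library on the CPM scale. The iron handling list there had 2 of 12 members higher and 3 lower past the size rule, and its median was not called. Xist stood at 1212 CPM in the Mg library and 588 in the Mg-TAGelMA library, and Y-linked genes had 0 and 53 UMIs.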
